A study of Mus musculus with 6 samples.

How the data were processed

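RNA was sequenced from Lineage−Sca1+cKit+CD34−Flk2− cells of C57BL/6 mouse bone marrow in 4 libraries, 1 for each combination of genotype (wild type, Twist1 cKO) and condition (steady state, 12 days after irradiation). The deposited values are FPKM per gene, 1 file per library, as made by the authors, with 30409 gene identifiers in each. The submitters' processing notes name Bowtie, BWA 0.7.12-r1039, MACS2 2.1.0, HOMER and the mouse build mm10 for the series as a whole. Which of these made the RNA-seq values, and how reads were counted, is not given in the sources used here. The 2 ATAC-seq samples of irradiated cells were not analysed here.

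Symbols were joined to 30231 identifiers, and 178 kept the identifier alone. Where 2 identifiers shared a symbol (6 symbols), the one with the higher mean was used. Differences were taken as log2 of FPKM + 1 on the values as deposited. Genes were kept in a comparison at 5 FPKM or more in the higher library, and those at least 2-fold apart on the log2 scale were counted. With 1 library per group no difference has a replicate check. A test of genotype over both conditions, which would leave 1 residual degree of freedom, was not run, and no p-value is given.

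Reads behind each value were recovered from the FPKM: for each gene the smallest whole numbers in the ratio of its 4 values, given 1 constant per library, which worked for 30406 of 30409 genes (99.99%). Any gene at 0 in all libraries counts as recovered without a check. The lengths found this way equalled the annotated lengths for 12 of 13 mitochondrial protein-coding genes. Recovered reads can be low by a whole factor. The procedure was tested on simulated data, where all reads were exact for 95.8% of 3479 genes with at least 30 reads over the libraries and for 88.5% of 2328 with fewer, and recovered totals were 98.9% to 99.1% of the simulated totals. The library sizes implied by the authors' values were 26031985 (wild type) and 25239648 (cKO) at steady state and 22146433 and 23450734 after irradiation, or 1.04, 1.14, 0.895 and 1.15 times the reads recovered in genes. Recovered reads were used for depth, for floors of 3 reads and for 95% counting intervals. These were Clopper-Pearson intervals for FPKM (reads out of the authors' library size) and for shares, and the conditional exact binomial interval for ratios. Where a library had 0 reads, the fold is a bound against the value of 3 reads.

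Before the data were examined, 48 gene lists were fixed: mitochondrial and metabolic pathways, ribosomes and proteasome, cell cycle, stem cell and progenitor identity, markers of other bone marrow cells, stress responses and reference genes. For each list with at least 4 genes kept, the median difference was placed among the medians of 10000 random lists, each gene replaced by 1 of the 100 genes nearest to it in mean level (seed 1). A list outside the central 95% was said to stand apart, which about 1 in 20 lists would do by chance if lists were random. The relative value of a list is its median minus the median of its random lists. Its interval is the order-statistic 95% interval of the list median less the same random median. Members at least 1.5-fold apart were counted. On simulated data with no difference, between 4.0% and 7.67% of lists stood apart, all lists raised by 0.15 were called high, all genes changed 4-fold were called, and between 4 and 9 unchanged genes were called per comparison. The simulated libraries differed by counting noise alone apart from the changes put in, and the simulated lists held genes drawn at random. These rates therefore do not carry over to real libraries or to lists of genes that vary together.

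Genes to be named were also set before the data were examined: the 12 highest and 12 lowest differences among genes with at least 10 FPKM in the higher library, leaving out microRNA, small nucleolar, predicted, ribosomal RNA, olfactory receptor, pseudogene, RIKEN and immunoglobulin or T cell receptor segment symbols, the last by the prefixes Tra, Trb, Trd and Trg, so Tcrg-C1 stayed in. Up to 4 genes of each list with the largest differences, 6 in each direction for the difference of differences, and a fixed set including Twist1, Runx1, Cacna1b, Cdkn1a, Ppargc1a and Hmox1 throughout completed the rule; 1 gene it takes in is not reported here. Positions are in GRCm38.

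Alternatives fixed in advance were pseudocounts of 0.1 and 5, minimum levels of 1 and 20 FPKM and none, scaling by the median of ratios and by the upper quartile, leaving out the 50 most abundant genes and rescaling the rest, removal of non-coding and predicted symbols, summing identifiers of a symbol, random lists without matching or matched on all 4 libraries, the mean over members, and removal of genes shared between lists. Added after the data were seen were scaling to recovered read totals, with and without immunoglobulin genes, centring on the median of all genes, removal of cell type markers and immunoglobulin genes, and matching random lists for gene length as well as level. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.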

Results

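RNA-seq was analysed from 4 libraries of cells sorted from mouse bone marrow as long-term haematopoietic stem cells (LT-HSCs, Lineage−Sca1+cKit+CD34−Flk2−). The libraries came from wild-type mice and from mice with a conditional knockout (cKO) of Twist1, which encodes a basic helix-loop-helix transcription factor, at steady state and 12 days after irradiation. There were no replicates: each of the 4 groups held 1 library, so differences are given as values with counting intervals, they have no replicate check, and no test between groups was run. The series also holds ATAC-seq of irradiated cells (2 samples), which was not analysed here. The values made by the authors are FPKM (reads scaled for gene length and library size) for 30409 genes. Reads recovered from them added up to 25099868 in the wild-type and 22126334 in the cKO library at steady state, and to 24743164 and 20349074 after irradiation. Genes above 0 FPKM made up 73.1% and 77.0% at steady state and 79.2% and 88.9% after irradiation (wild type and cKO in each pair). Differences below are on the log2 scale of FPKM + 1 unless called folds, which are ratios of FPKM with exact 95% intervals. Counts of genes at least 2-fold or 1.5-fold apart were also taken on the log2 scale of FPKM + 1. Intervals and floors cover counting error only.

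Twist1 (ENSMUSG00000035799, GRCm38 chromosome 12, 33957671 to 33959831) was close to absent in all 4 libraries. At steady state it had 6 reads in the wild-type library, 0.143 FPKM (0.0523 to 0.310), and 2 reads in the cKO library, 0.0490 FPKM (0.00594 to 0.177). After irradiation it had 5 reads in the wild-type library, 0.140 FPKM (0.0454 to 0.326), and 0 reads in the cKO library, where 3 reads would have given 0.0792 FPKM. Whether the measured part of the gene lies within the deleted part is not given in the sources used here. Ly6a, which encodes the Sca1 antigen of the sorting gate, had 534 and 362 FPKM at steady state and 89.1 and 256 FPKM after irradiation (wild type first). Xist, transcribed from the inactive X chromosome, had 0.0171 and 0.0155 FPKM in the steady-state libraries and 1.003 and 0.573 FPKM after irradiation (wild type first). The Y-linked Ddx3y had 10.2 and 12.4 FPKM at steady state and 0.0521 and 0.0164 FPKM after irradiation, so sex-linked transcripts divided the libraries exactly as irradiation did.

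**Figure D1:**
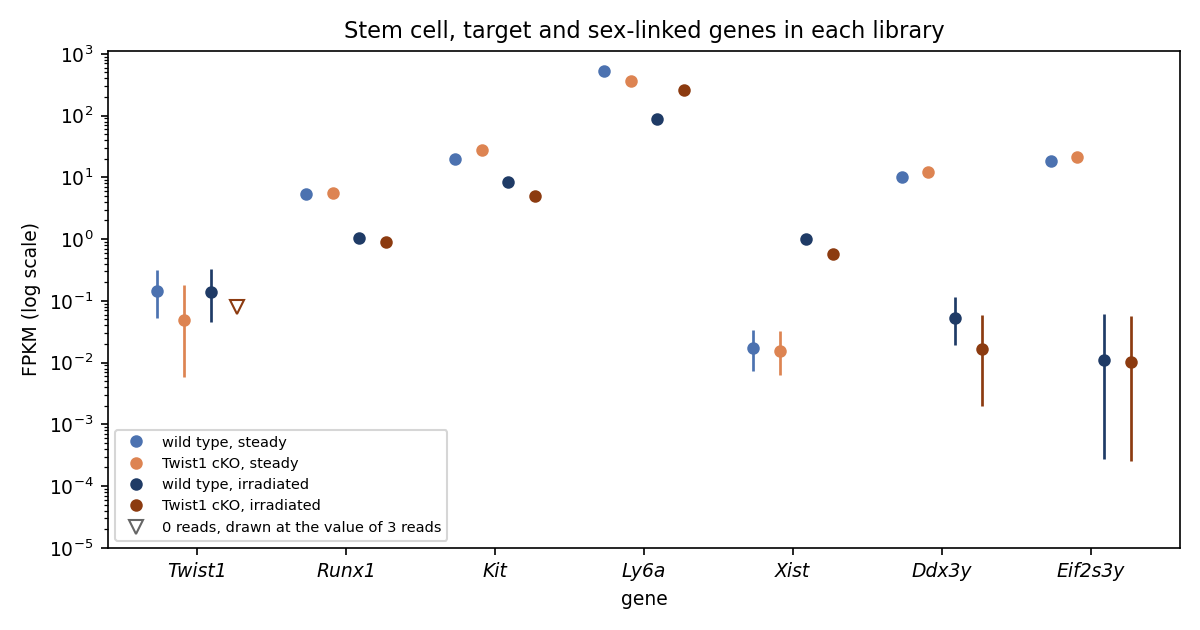
FPKM (log axis) of target, stem cell and sex-linked genes in each of the 4 libraries, with lines for exact 95% counting intervals and an open triangle at the value of 3 reads where a library had 0 reads. Runx1 stood at 5.45 and 5.65 FPKM at steady state and at 1.03 and 0.891 FPKM after irradiation (wild type and cKO), while Ddx3y and Xist parted the irradiated from the steady-state libraries in opposite directions.

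The first comparison asked what loss of Twist1 goes with in unstressed LT-HSCs. Twist1 itself was 2.91-fold lower in the cKO library with an interval of 0.520 to 29.5, so the counts did not settle a difference. Macrophage transcripts were lower in the cKO library: the chains of complement C1q, made by tissue macrophages, lay 3.58-fold (3.38 to 3.79) lower for C1qa and 3.27-fold (3.17 to 3.38) lower for C1qb. Transcripts of the neutrophil list were higher, with Ngp, neutrophilic granule protein, at 546 against 225 FPKM (2.43-fold, 2.36 to 2.49) and Chil3, a secreted chitinase-like protein, at 2.83-fold (2.68 to 2.99), whereas the early myeloid granule genes Ctsg (−0.57) and Elane (−0.40) were lower. Nuclear genes of oxidative phosphorylation were lower by a small amount, with a list median of −0.33 over 76 genes that became −0.13 over 75 genes when the 50 most abundant genes were left out and the rest rescaled, and −0.19 with recovered read totals. Transcripts of LT-HSC identity were slightly higher, with a list median of 0.16 over 25 genes.

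Of 7157 genes with at least 5 FPKM in the higher library, 46 were at least 2-fold higher and 193 at least 2-fold lower in the cKO library (19.2% higher among these), and the median over all genes was 0.01. Leaving out the 50 most abundant genes and rescaling the rest, which brought 8674 genes to 5 FPKM, the split was 98 higher and 160 lower (38.0% higher), and with recovered read totals as the scale it was 68 and 160 (29.8%). Among the genes with the largest positive differences, mt-Co1, the mitochondrially encoded subunit 1 of cytochrome c oxidase, had 733 against 146 FPKM (5.01-fold, 4.87 to 5.15). Granule and neutrophil products followed with Retnlg (1.81), Chil3 (1.48), Ltf, which encodes lactoferrin (1.34), Ngp (1.27) and Lcn2, which encodes lipocalin 2 (1.08). The remaining highest genes were the histone gene Hist1h2bg (1.29), the chemokine gene Ccl3 (1.13), the AP-1 subunit gene Jun (1.03), the arginine methyltransferase gene Prmt1 (0.92), Nudt3 (0.91) and the histone chaperone gene Rbbp4 (0.91). Rpl29, a protein of the large ribosomal subunit, was the lowest (−2.08), at 18.2 against 80.3 FPKM. Macrophage products made up most of the other lowest genes: the lectin gene Cd209f (−1.91), C1qa (−1.82), the ficolin gene Fcna (−1.80), the chemokine gene Ccl8 (−1.77), Cd5l (−1.71), C1qb (−1.71), C1qc (−1.70) and Aif1 (−1.65). The protease inhibitor gene Slpi (−1.73), Cotl1 (−1.63) and the eotaxin receptor gene Ccr3 (−1.63) completed that group.

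The nuclear oxidative phosphorylation list lay 0.18 below 10000 random lists matched for expression level (relative value −0.18, interval of the relative value −0.24 to −0.13, percentile 0), as a description of these libraries. Of its 76 genes, 74 lay below the median of all genes. Abundant genes in general were lower in the cKO library (Spearman's rho of −0.24 between mean level and difference over all genes). Counts against that median, here and by complex, thus do not separate the list from genes of like level. Only 1 of the 76 was at least 1.5-fold lower: Atp5k, a subunit of ATP synthase (−0.64). Atp5j2 of the same enzyme (−0.52), Ndufc1 of complex I (−0.52) and Cox7c of complex IV (−0.52) came next. By complex, complex I was lower by −0.20 relative to random lists (34 of 35 genes below the median of all genes), complex IV by −0.19 (12 of 12) and complex V by −0.18 (16 of 16), whereas complex II and complex III stayed inside the central 95%. Mitochondrial ribosomal proteins (76 genes, relative −0.19, percentile 0) and cytosolic ribosomal proteins (62 genes, relative −0.14, percentile 0.02) were lower too, including Mrpl52 (−0.58), Rps21 (−0.61) and Rplp2 (−0.60). The tricarboxylic acid cycle list (0.05 over 21 genes), fatty acid oxidation, glycolysis and the 11 mitochondrially encoded genes (median 0.05) did not stand apart. Ppargc1a, a coactivator of mitochondrial biogenesis, had 0.313 against 0.280 FPKM, a ratio of 1.12 (0.740 to 1.69). The oxidative phosphorylation and ribosomal lists hold mostly short genes, and shorter genes in general were lower in the cKO library, with a Spearman's rho of 0.36 between gene-model length and the difference over all genes and of 0.52 within the oxidative phosphorylation list. Averaging over members in place of the median ended the call for that list (relative −0.07, percentile 15.8) and for the complexes and both ribosomes; among all lists, only the neutrophil, macrophage, B cell, stromal and immediate early calls held under every alternative, the stromal list being too small to run at a minimum of 20 FPKM.

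**Figure D2:**
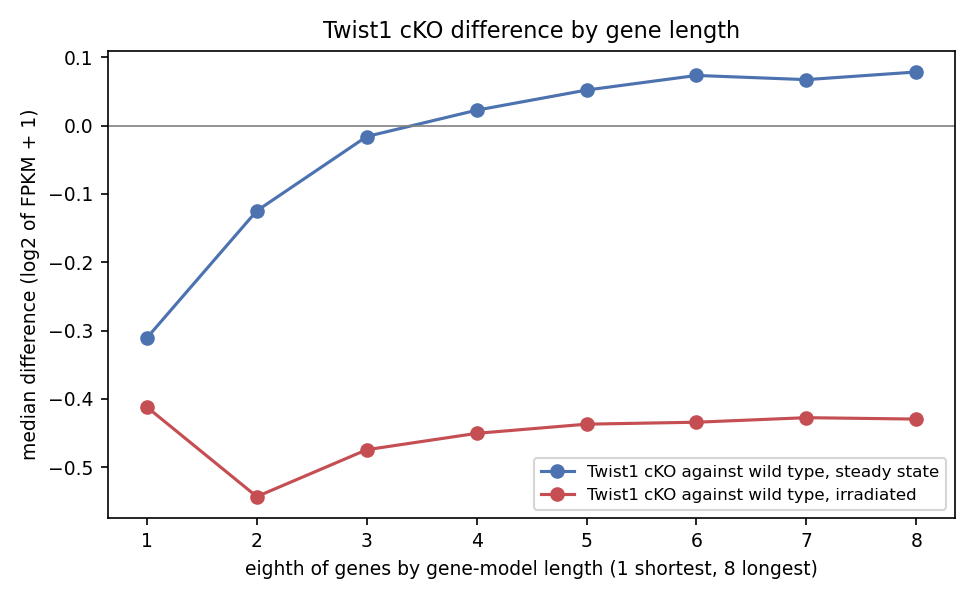
Median difference between the Twist1 cKO and the wild-type library (log2 of FPKM + 1) in each eighth of genes ordered by gene-model length, at steady state and after irradiation. At steady state the medians ran from −0.31 in the shortest eighth to 0.08 in the longest, whereas after irradiation all lay between −0.54 and −0.41.

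Markers of other cell types moved in both directions at steady state. The macrophage, monocyte and dendritic cell list was lowest (−1.36 over 15 genes, −1.70 to −0.94), with 13 genes at least 1.5-fold lower. B cell and plasma cell genes were lower (−0.56 over 10 genes, 5 at least 1.5-fold), among them Mzb1 (−1.05) and Jchain, which joins IgA and IgM multimers (−0.86). The erythroid list was lower (−0.33 over 17 genes, 5 at least 1.5-fold), with the globin genes Hba-a1 (−1.42) and Hbb-bs (−1.42). All 5 stromal genes kept were lower by at least 1.5-fold (median −0.71), among them Ibsp (−1.02) and Adipoq (−0.86). MHC class II genes had a median of −0.51 over 8 genes, with Cd74, the invariant chain, at −0.94, and 1 member higher. Neutrophil genes were higher (0.67 over 13 genes, 0.30 to 1.34, 8 at least 1.5-fold). Immunoglobulin transcripts took 14.7% of the reads in the wild-type library and 9.87% in the cKO library, and haemoglobin transcripts 0.114% and 0.0474% (exact Clopper-Pearson intervals are drawn in the plot of these shares).

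Within the LT-HSC identity list, 18 of 25 genes lay above the median of all genes and none was 1.5-fold apart. Hoxa9 (0.47), the stem cell factor receptor gene Kit (0.44) and Procr, which encodes the endothelial protein C receptor (0.36), were higher, while Ly6a was lower at 362 against 534 FPKM (−0.56). With a minimum of 1 FPKM that list was no longer apart (percentile 84.9). Runx1, a regulator of definitive haematopoiesis, differed little (1.04-fold, 0.968 to 1.11). Immediate early genes were higher (0.19 over 24 genes, 4 at least 1.5-fold), led by Jun, Klf6 (0.87) and Klf2 (0.83). Hmox1, which degrades haem and is abundant in macrophages, was 2.57-fold (2.44 to 2.72) lower, whereas p53 targets did not stand apart and Cdkn1a, the p21 inhibitor, had 68.8 against 79.4 FPKM. The S phase, heat shock and endothelial lists were also high (0.09, 0.11 and 0.21), and the interferon response list was low (−0.11), a direction that turned with scaling (−0.14 to 0.08).

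**Figure D3:**
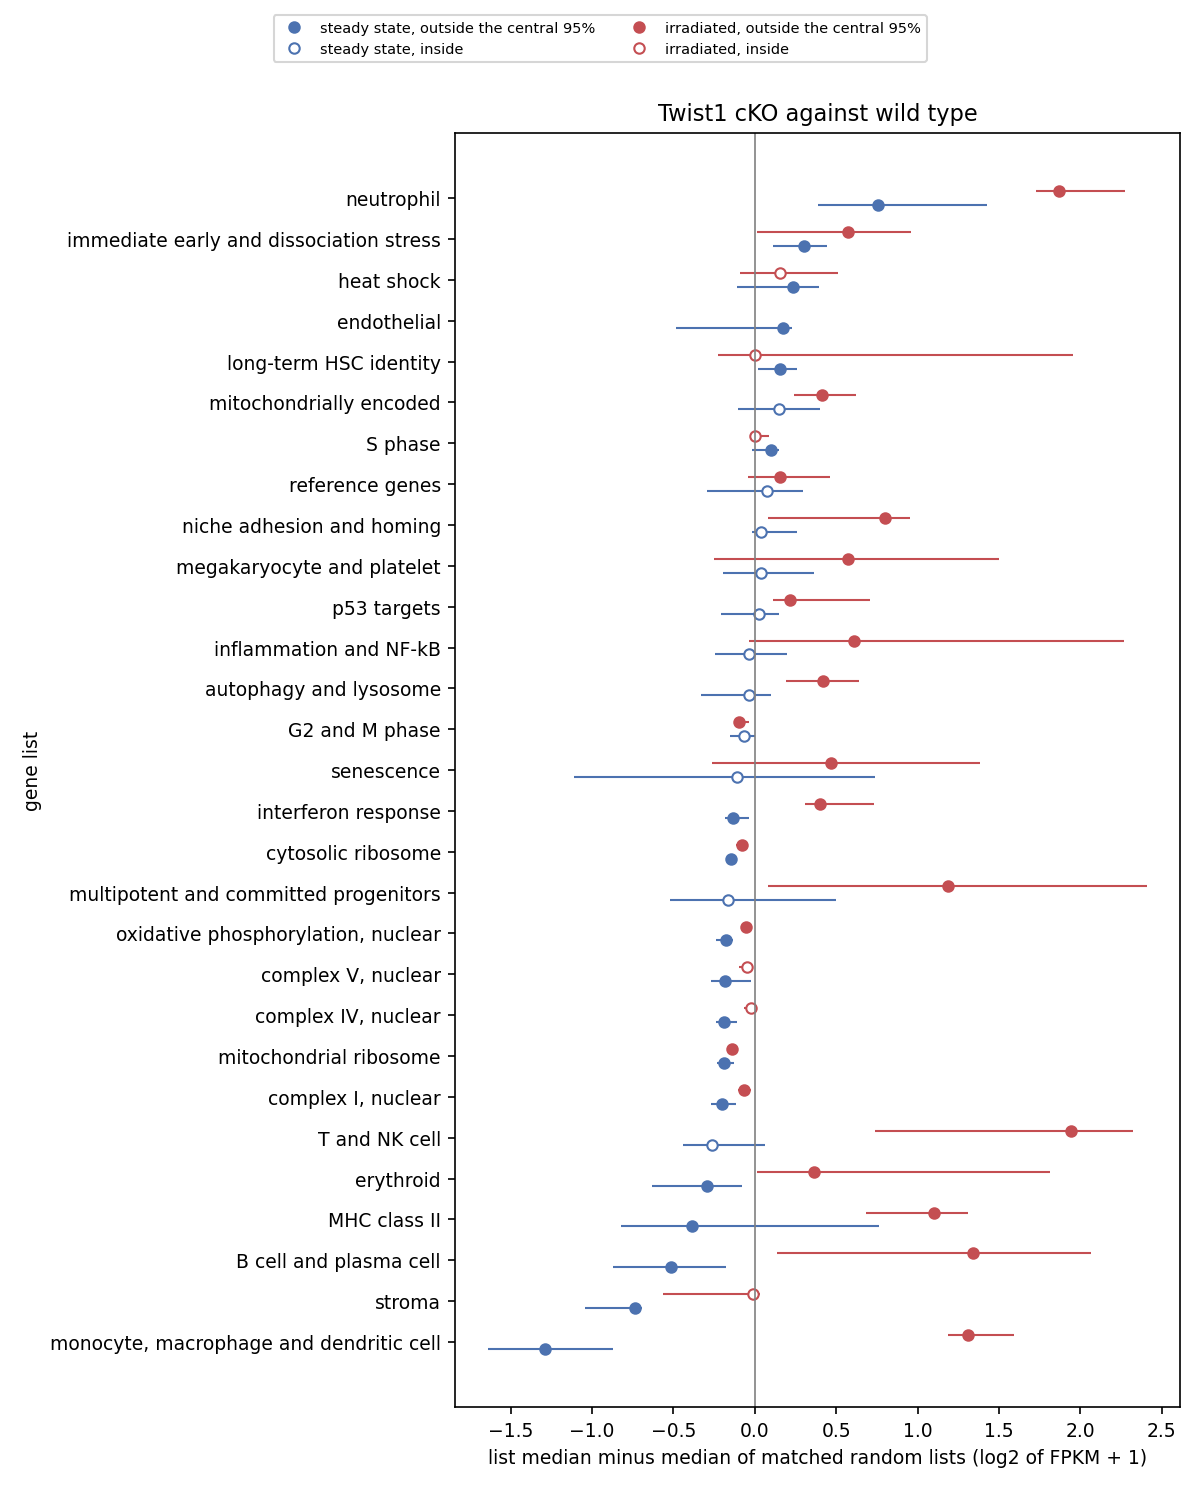
Median of each gene list minus the median of its matched random lists (log2 of FPKM + 1) for Twist1 cKO against wild type, with lines for order-statistic 95% intervals and filled points for lists outside the central 95% of random lists. Macrophage and B cell lists lay below 0 at steady state (−1.29 and −0.51) and above 0 after irradiation (1.31 and 1.34), and nuclear oxidative phosphorylation lay below 0 in both (−0.18 and −0.05).

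The second comparison asked the same of cells taken 12 days after irradiation. Twist1 had 0 reads in the cKO library and was at least 1.76-fold lower there at a floor of 3 reads, although the interval of the ratio reached down to 0.970. Relative to the median of all genes, transcripts of most mature blood lineages were higher in the cKO library: S100a8, a neutrophil calcium-binding protein, had 411 against 117 FPKM (1.81), the macrophage lysozyme gene Lyz2 1052 against 485 FPKM (1.11), and Jchain 4264 against 1423 FPKM (1.58). Granule enzyme genes of early myeloid cells were higher as well, with the myeloperoxidase gene Mpo at 5.63-fold (4.85 to 6.55) and the elastase gene Elane at 3.99-fold (3.45 to 4.63). Genes of respiration and translation were lower beyond the general shift by a small amount, with −0.05 for nuclear oxidative phosphorylation and −0.14 for the mitochondrial ribosome.

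The median difference over all 6348 genes was −0.45, and other scalings moved it to between −0.40 and −0.02, so list values here are relative to matched random lists. Values of single genes were not adjusted and include this general shift. At least 2-fold higher in the cKO library were 284 genes and lower were 66 (81.1% higher). Centred on the median of all genes the split was 489 and 30 (94.2%), and with recovered read totals it was 470 and 32 (93.6%). Ldlrad4, an inhibitor of TGF-beta signalling, was highest at 31.4 against 1.58 FPKM (19.9-fold, 16.1 to 25.0). The other highest genes were Retnlg (2.69), the lymphocyte GTPase genes Gimap3 (2.23) and Gimap4 (5.15-fold, 4.18 to 6.40), Ifitm6 (2.14), Mpo (2.13), the collagen gene Col13a1 (2.07), Elane (1.95), the scavenger receptor gene Marco (1.90), the cathepsin G gene Ctsg (1.86) and the chemokine genes Ccl4 (1.85) and Ccl5 (1.84). Lowest were Nr4a1, an immediate early nuclear receptor (−1.42), the osteocalcin gene Bglap2 (−1.35), Ttc4 (−1.33), Anp32a (−1.28), Car1, an erythroid carbonic anhydrase (−1.19), and Osm, the cytokine oncostatin M (−1.17). Adat2 (−1.12), Ccnb1ip1 (−1.06), Socs1 (−0.99), Snhg8 (−0.97), Myc (−0.96) and Gdf3 (−0.96) made up the rest.

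Nuclear oxidative phosphorylation genes had a median of −0.67 over 76 genes against −0.62 for their random lists, a relative value of −0.05 (−0.07 to −0.03, percentile 0.56). Of the 76, 74 lay below the median of all genes. Abundant genes in general were lower here too (Spearman's rho of −0.38 between mean level and difference), so that count does not separate the list from them. Ndufc1 (−0.82), Atp5k (−0.81), Uqcr10 of complex III (−0.80) and Atp5g1 (−0.80) were lowest. Complex I alone stood apart among the complexes (relative −0.07), and within the whole list longer genes were less reduced (rho 0.29). Mitochondrial ribosomal proteins (77 genes, relative −0.14), cytosolic ribosomal proteins (62 genes, relative −0.08) and G2 and M phase genes (38 genes, relative −0.10) were lower too, with Mrps24 (−0.85), Rps21 (−0.90) and the mitotic cyclin gene Ccnb2 (−0.70). The mitochondrially encoded genes were higher relative to random lists (0.41 over 10 genes), although their plain median of −0.14 turned to 0.30 with scaling. Ppargc1a had 0.252 against 0.151 FPKM, a ratio of 1.67 (0.968 to 2.96).

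Markers of mature cells stood high beside all of these lists. Relative to random lists the values were 1.94 for T and NK cells (7 genes), 1.87 for neutrophils (11 genes), 1.34 for B and plasma cells (8 genes), 1.31 for macrophages, monocytes and dendritic cells (14 genes) and 1.10 for MHC class II (7 genes). In the T and NK list, Cd7 (5.49 against 0.678 FPKM), Trbc1 (7.52 against 1.45), Cd3g and Trbc2 reached the minimum of 5 FPKM in the cKO library alone. Their being kept is thus tied to the direction of their difference. Examples were the T cell receptor gene Trbc1 (1.80), S100a9 (1.54), Cd79a of the B cell receptor (1.14), and Adgre1, which encodes the macrophage antigen F4/80 (1.22). Multipotent and committed progenitor genes had a relative value of 1.18 (9 genes, 5 at least 1.5-fold higher and 1 lower). Erythroid genes had 0.36 over 19 genes, 8 higher and 4 lower by at least 1.5-fold, with Alas2, the first enzyme of haem synthesis in red cells (1.51), and Hbb-bs (1.28) higher. Their plain median was −0.20 and turned to 0.26 with scaling, and their mean was 0.23. Immunoglobulin reads made up 8.87% of the cKO library against 2.71%, and haemoglobin reads 1.13% against 0.377%. Genes of olfactory receptors, which blood cells barely transcribe, had at least 1 read in 74.3% of cases in the cKO library against 51.7% in the wild-type library.

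**Figure D4:**
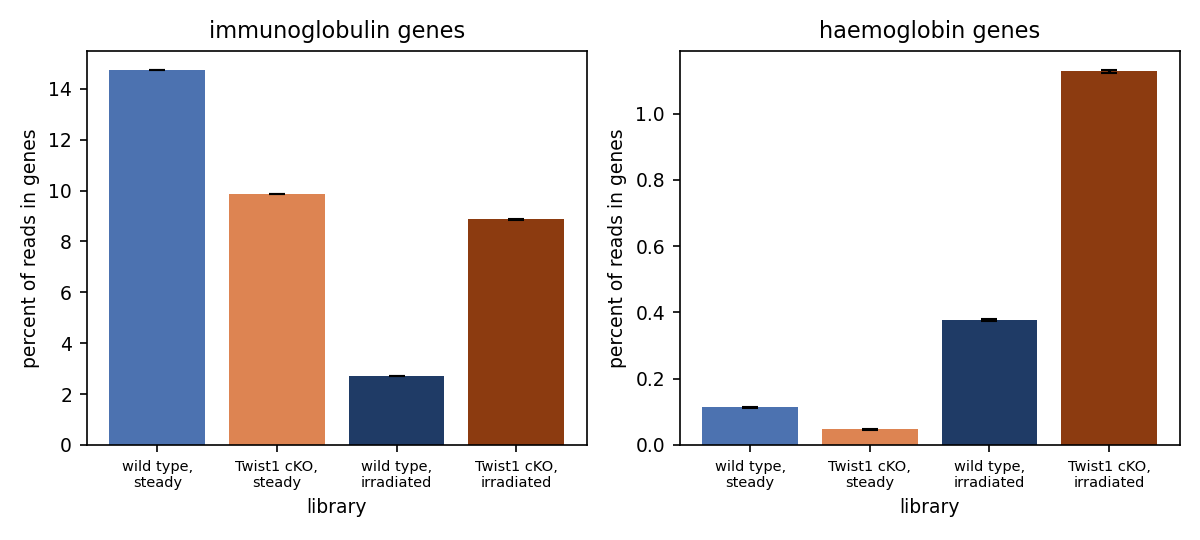
Percent of recovered reads that fell in immunoglobulin genes (275 genes) and haemoglobin genes (9 genes) in each library, with Clopper-Pearson 95% intervals. The cKO library held less of both at steady state (9.87% against 14.7%, and 0.0474% against 0.114%) and more of both after irradiation (8.87% against 2.71%, and 1.13% against 0.377%).

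LT-HSC identity genes did not stand apart between the irradiated libraries, where only 7 were kept, and they went both ways: Ly6a was higher at 256 against 89.1 FPKM (1.51), and Kit was lower at 4.98 against 8.52 FPKM (−0.67, beside a median of −0.45 over all genes). Runx1 had 0.891 against 1.03 FPKM (−0.10), a direction that turned with scaling (0.07 with recovered read totals). Interferon response genes were higher relative to random lists (0.40 over 23 genes), with Rsad2 (1.10), an antiviral radical SAM enzyme; their plain median of −0.05 turned to 0.41 with scaling, and their mean was 0.11. Lists of inflammation (0.61), niche adhesion (0.80), senescence (0.47), autophagy and lysosome (0.42), megakaryocytes (0.57), p53 targets (0.21) and reference genes (0.15) were higher relative to random lists as well. Plain medians of p53 targets (−0.20 to 0.19), autophagy and lysosome (−0.07 to 0.37) and reference genes (−0.43 to 0.02) changed sign with scaling, and the plain senescence median of 0.01 had a mean of −0.01. Averaging over members ended the calls of complex I, G2 and M phase, mitochondrially encoded, T and NK cell and interferon genes and of these other lists except inflammation. Further alternatives ended the calls of senescence (minimums of 1 and 20 FPKM and none, without shared genes), megakaryocytes (no minimum, no matching, matching on all 4 libraries), p53 targets (no minimum, without shared genes), G2 and M phase (a minimum of 20 FPKM) and reference genes (4 alternatives). Immediate early genes stood at 0.57 relative to random lists, a call also ended by averaging, and were mixed, with Klf2 (1.78) and Klf6 (1.08) higher and Nr4a1 and Myc lower. Cdkn1a had 36.6 against 29.5 FPKM (1.24-fold, 1.16 to 1.33) and Hmox1 112 against 65.7 FPKM (1.71-fold, 1.64 to 1.78). Cacna1b, the pore subunit of an N-type voltage-gated calcium channel, had 39 reads against 2, a ratio of 18.4 (4.77 to 157) at 0.167 against 0.00908 FPKM. These levels lie far below the minimum of 5 FPKM. Scarce genes had more reads in this cKO library more widely, with 1899 against 857 reads in olfactory receptor genes.

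The third comparison asked how wild-type cells sorted as LT-HSCs 12 days after irradiation differ from those at steady state. Twist1 had 0.140 against 0.143 FPKM. Several stem cell transcripts were nearly absent from the irradiated library: Procr, the endothelial protein C receptor gene, had 0.333 against 51.3 FPKM (−5.29), and the homeobox gene Nkx2-3 had 0 against 4341 reads, at least 1231-fold lower at a floor of 3 reads. Erythroid and mitotic transcripts were higher, with the erythroid transcription factor gene Klf1 at 703 against 93.5 FPKM (2.90) and the mitotic cyclin gene Ccnb1 at 162 against 23.9 FPKM (2.71). Mitochondrial chaperone and respiratory genes were higher in the same library, with Hspe1 at 1193 against 188 FPKM (2.66) and Cyc1, cytochrome c1, at 929 against 254 FPKM (1.87).

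Of 7418 genes, 1400 were at least 2-fold higher and 1401 at least 2-fold lower, with a median of 0.21 (49.98% higher). That split depended on the scale: 942 and 1668 when centred on the median (36.1%), 2960 and 906 with upper-quartile scaling (76.6%, median 0.77), and 750 and 2297 without the 50 most abundant genes (24.6%, median −0.24). The highest genes were Tcrg-C1, a T cell receptor gamma constant segment (6.71, 1969 against 17.8 FPKM), Cda, cytidine deaminase (5.89), C2cd4a (5.51), Cask (3.72), Plek2 (3.70), the metallothionein genes Mt2 (3.55) and Mt1 (3.09), and Prl2c5 (3.48). Rhag of the red cell membrane (3.35), Epdr1 (3.16), the Wnt antagonist gene Sfrp4 (3.12) and Bglap2 (3.03) followed. Among the lowest genes were Gng11 (−6.36), Nkx2-3 (−6.32), Myct1 (−6.21), Ctla2b (−5.87), Ifitm1 (−5.77), the myeloid granule genes Mpo (−5.61) and Elane (−5.44), Ldhb (−5.51), the keratin gene Krt18 (−5.39), Pdzk1ip1 (−5.31) and Cd27 (−5.31). 

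LT-HSC identity genes had a median of −3.13 over 24 genes, 22 of them at least 1.5-fold lower, in the library that also differed in sex-linked transcripts, so its name as LT-HSC rests on the sorting gate and not on these genes. Megakaryocyte genes (−3.76 over 11 genes), progenitor genes (−2.69 over 14), immediate early genes (−2.35 over 24), quiescence genes (−1.93 over 15) and mast cell genes (−3.31 over 5) were low as well. The megakaryocyte list includes Pf4, platelet factor 4 (−4.50), and the quiescence list includes Cdkn1c, which encodes p57 (47.6-fold lower, 24.0 to 111). Runx1 was 5.29-fold (4.65 to 6.04) lower. Erythroid genes were high (1.85, 16 of 18 genes), among them Tfrc, the transferrin receptor (2.43). Cycling genes were high in both phases, with G2 and M phase at 1.54 (36 of 38 genes, Plk1 2.35) and S phase at 1.02 (26 of 30 genes, Ccne1 2.23).

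Nuclear oxidative phosphorylation genes had a median of 1.03 (0.96 to 1.15), with 72 of 76 at least 1.5-fold higher. Random lists of like abundance were high too, so the relative value was 0.19 (percentile 98.0), and it lay inside the central 95% in 5 alternatives, among them a minimum of 20 FPKM, a pseudocount of 5 and matching for gene length. Complex III stood apart (1.45 over 9 genes), with Uqcr11 (1.77), whereas the other complexes stayed inside. The mitochondrial ribosome (1.18, relative 0.59, Mrpl12 2.02), mitochondrial import and chaperones (1.54, relative 0.81, Hspd1 2.28) and proteasome (1.22, relative 0.41, Psmb3 1.78) were higher. Mitochondrially encoded genes were lower (−0.61 over 11 genes), except mt-Co1 (1.20), although averaging over members ended that call. Genes of DNA repair (0.79, H2afx 1.54) and of mTORC1 and amino acid stress (1.24, Asns 2.42) were higher. Markers of mature cells were lower: neutrophils −2.23 (11 of 11 genes), B and plasma cells −1.79 (10 of 10), macrophages −0.99 (14 of 16), MHC class II −1.30 (6 of 8) and stroma −1.53 (4 of 6). Inflammation (−1.22), interferon response (−0.92, Irf1 −2.35) and niche adhesion (−1.24) were lower, and autophagy and lysosome genes had −0.40, which scaling turned to 0.17. Alternatives also ended the calls of DNA repair (a minimum of 20 FPKM), mTORC1 (no minimum), stroma (no minimum, averaging), autophagy and mitochondrially encoded genes (no matching), and niche adhesion and quiescence (without genes shared with another list). Cdkn1a was 2.69-fold (2.54 to 2.86) lower and Hmox1 1.31-fold (1.25 to 1.37) lower, the latter turning to 0.15 on the log2 scale with upper-quartile scaling.

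**Figure D5:**
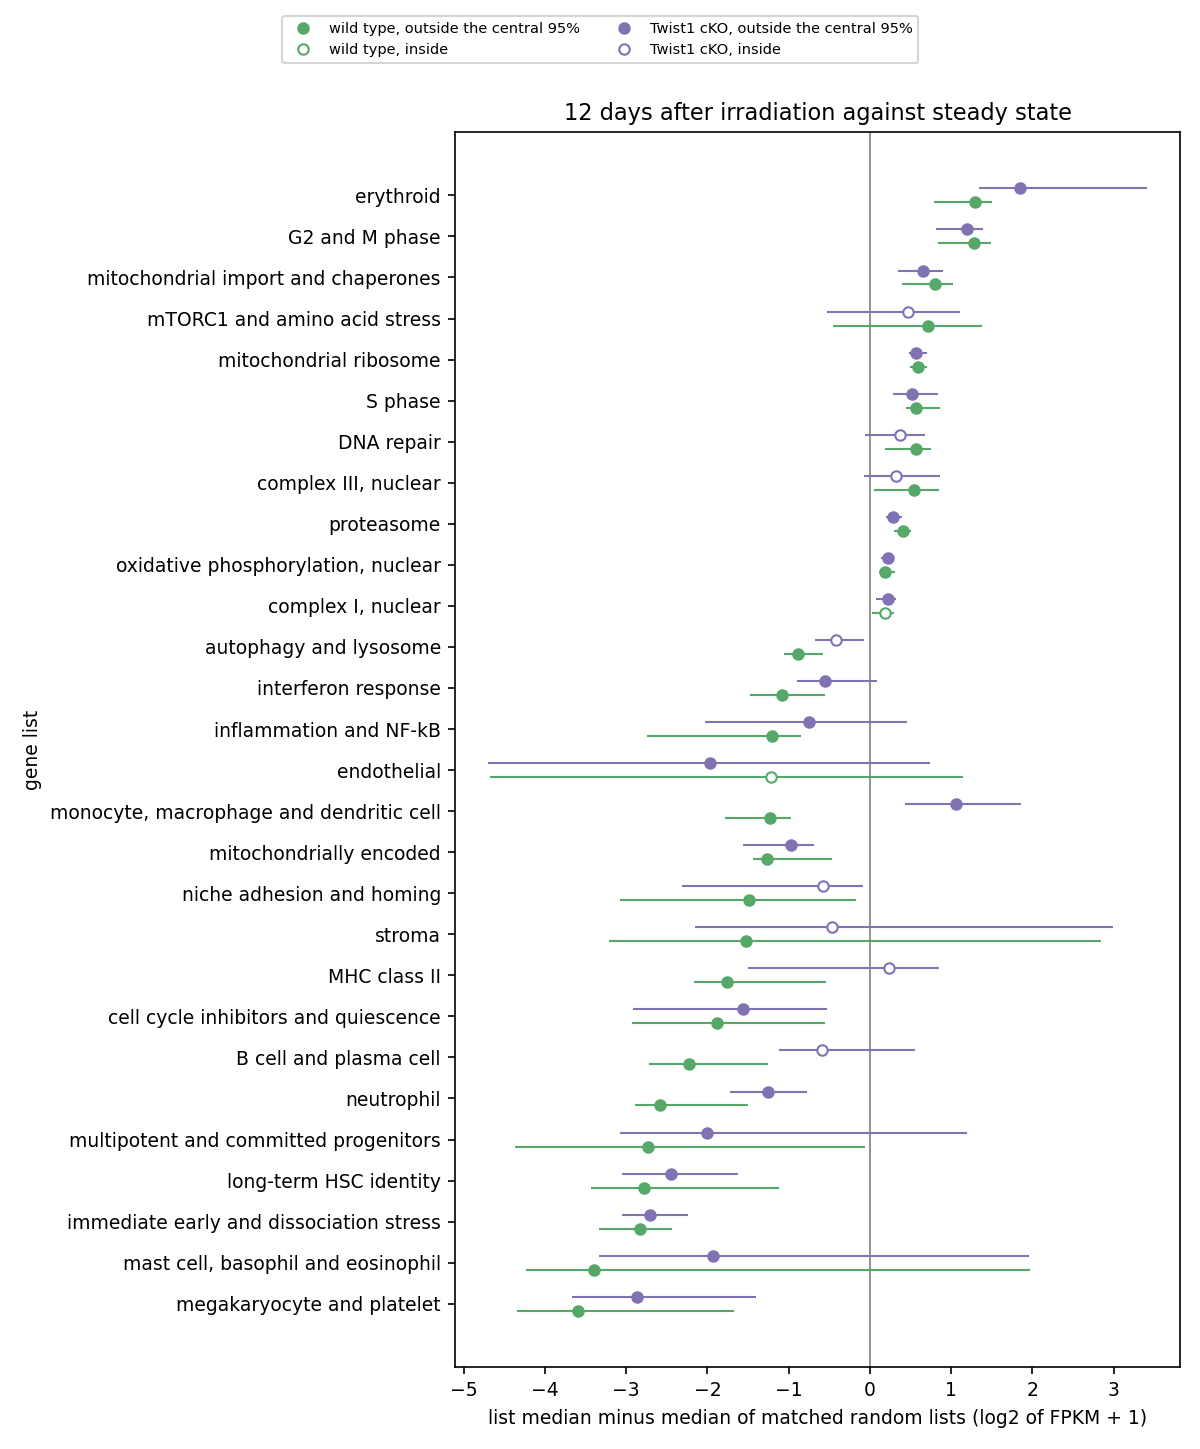
Median of each gene list minus the median of its matched random lists (log2 of FPKM + 1) for irradiated against steady-state cells of each genotype, with lines for order-statistic 95% intervals and filled points outside the central 95% of random lists. LT-HSC identity was low in both (−2.78 in wild type, −2.45 in cKO), erythroid genes were high in both (1.29 and 1.85), and the macrophage list was low in wild type (−1.23) and high in cKO (1.06).

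The fourth comparison set irradiated against steady-state cells of Twist1 cKO mice. Twist1 had 0 against 2 reads, both under the floor of 3 reads, so no fold is given. As in wild type, several stem cell transcripts were nearly absent, with Nkx2-3 at 0 against 3670 reads, at least 1137-fold lower at a floor of 3 reads. Globin transcripts were far higher: Hba-a1, an alpha globin, had 6074 against 255 FPKM (23.9-fold, 23.2 to 24.5) and Hbb-bs, a beta globin, 3563 against 143 FPKM (24.8-fold, 24.0 to 25.7). Marco of macrophages had 65.4 against 0.309 FPKM (212-fold, 128 to 379).

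Here 762 of 7393 genes were at least 2-fold higher and 1673 at least 2-fold lower (31.3% higher), with a median of −0.20. Centred on the median the split was 1070 and 1358 (44.1%), with the median of ratios 1205 and 1278 (48.5%), and with upper-quartile scaling 2066 and 861 (70.6%, median 0.46). The highest genes were Marco (5.67), Tcrg-C1 (5.27), Cda (5.14), Hbb-bs (4.62), Hba-a1 (4.57), Hba-a2 (4.41), Hbb-bt (4.35), C2cd4a (4.28), Col13a1 (4.17), the defensin gene Defb26 (3.86), Rpl29 (3.80) and Alas2 (3.65). Among the lowest were the cathepsin inhibitor genes Ctla2a (−6.51) and Ctla2b (−5.19), Myct1 (−6.28), Nkx2-3 (−6.13), the adhesion receptor gene Adgrl4 (−5.88), Ifitm1 (−5.71), Pcp4l1 (−5.53), Gng11 (−5.47), Nr4a1 (−5.46), the angiopoietin gene Angpt1 (−5.33), and Krt18 (−5.30).

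LT-HSC identity genes had a median of −2.98 over 25 genes, 22 of them at least 1.5-fold lower, with Procr at 1.22 against 66.1 FPKM (−4.92). In both genotypes 13 of 38 identity genes lay below 5% of their steady-state level at the upper bound of the counting interval, whereas Gfi1b stood at 239% of its steady-state FPKM in wild type and 165% in cKO, and the same sex-linked split ran between these libraries. Ly6a kept 70.7% of its steady-state FPKM in cKO and 16.7% in wild type. Megakaryocyte (−3.25 over 12 genes), progenitor (−2.20 over 14), immediate early (−2.54 over 23), quiescence (−1.89 over 14), mast cell (−2.31 over 5) and endothelial genes (−2.35 over 7) were low, among them the CD34 antigen gene Cd34 (−4.51) and Egr1 (−3.78). Leaving out genes shared with another list moved the endothelial list inside the central 95%. Runx1 was 6.35-fold (5.55 to 7.28) lower. Erythroid genes were high (2.09, 18 of 19 genes), as were G2 and M phase (1.08, 27 of 36, Ube2c 2.01) and S phase genes (0.53, 14 of 30, Rrm2 1.78).

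Nuclear oxidative phosphorylation genes had a median of 0.70 (0.62 to 0.77), with 50 of 76 at least 1.5-fold higher and a relative value of 0.22 (percentile 99.8), led by Atp5g1 (1.52) and Uqcr11 (1.42). Complex I stood apart (0.65 over 35 genes) in the chosen settings, and 13 alternatives ended that call. The mitochondrial ribosome (0.71, relative 0.57, Mrpl20 1.39), import and chaperones (0.92, relative 0.66, Hspe1 2.20) and proteasome (0.74, relative 0.28, Psmb3 1.35) were higher, and the 10 mitochondrially encoded genes lower (−0.65). Macrophage genes were higher (relative 1.06, 9 of 15 genes), among them Fcgr1, an Fc receptor (1.97), and Cx3cr1, the fractalkine receptor (2.09). Neutrophil (−1.07, 10 of 13 genes), inflammation (−1.07) and interferon response genes (−0.83, 19 of 31) were lower, although Ifi27l2a was higher (2.88) and averaging over members ended the interferon call. The inflammation call ended without the 50 most abundant genes and without shared genes, and others that ended were mast cells (averaging, read totals excluding immunoglobulins), S phase (a minimum of 20 FPKM) and mitochondrially encoded genes (no matching). Hmox1 was 3.35-fold (3.18 to 3.54) higher and Cdkn1a 1.88-fold (1.78 to 1.99) lower. Shorter genes were higher in this comparison, with medians of 0.37 in the shortest and −0.39 in the longest eighth of genes.

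The last comparison set the cKO difference after irradiation against that at steady state, gene by gene over 7772 genes. The 2 differences were weakly related and the sign hung on the measure, with a Pearson's r of −0.187 and a Spearman's rho of 0.160 over genes, which are not independent of one another. Genes with the largest positive shift were Ldlrad4 (3.34), Cd209f (3.03), Marco (3.02), Slpi (2.91), Cd5l (2.86) and Hba-a2 (2.79). The most negative were mt-Co1 (−2.09), Nr4a1 (−1.74), Prmt1 (−1.56), Tcrg-C1 (−1.45), Osm (−1.38) and Ccnb1ip1 (−1.36). By list, 4 were low in the cKO library under both conditions (nuclear oxidative phosphorylation, complex I, mitochondrial ribosome, cytosolic ribosome), 2 were high in both (neutrophil and immediate early genes) and 5 went opposite ways. The oxidative phosphorylation list stood 0.08 above random lists in this difference (percentile 98.97), a sign that reversed when members were averaged (−0.16), and its plain median of −0.35 turned to 0.05 with scaling.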

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

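In this part, matching random lists for gene length was added after the oxidative phosphorylation pattern was seen, though how to read it was set before its own result; the other tests, that of length within the list included, were chosen only after the result was seen. The 5 lists named next had cKO differences in opposite directions at steady state and after irradiation, relative to matched random lists, and the difference between the conditions was not tested, since each group held 1 library. The macrophage, monocyte and dendritic cell list had a difference of differences of 2.12. B cell and plasma cell genes had 1.35. MHC class II genes had 0.92. Interferon response genes had 0.17, and erythroid genes had 0.14, against about −0.4 for random lists, and the plain medians of these last 2 lists were below 0 under both conditions.

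The first pattern weighed was the lower level of nuclear oxidative phosphorylation transcripts in both cKO libraries. At steady state the list lay below genes of like level and gene-model length: against random lists matched on both, it stayed at −0.18 (percentile 0). That does not exclude a bias tied to length. The matching kept 15 of 18 calls and ended only those of high lists (S phase, heat shock, endothelial). It was thus not shown to remove a deficit of short genes. After irradiation this matching moved next to nothing (all 22 calls kept), so its −0.05 decides nothing. RNA from macrophages and plasma cells that is richer in these transcripts than the irradiated cells themselves is argued against for the irradiated pair. Those markers stood high in the irradiated cKO library while the list stood at −0.05. The level of these transcripts in macrophages and plasma cells was not measured, and in wild type the list itself was higher after irradiation. RNA richer than steady-state cells but poorer than irradiated cells was therefore not excluded as a cause of both. At steady state, where markers and list were all low in cKO, RNA from macrophages and plasma cells stays open. So does RNA from erythroid cells, whose markers went both ways after irradiation (4 of 19 at least 1.5-fold lower). Cells poor in these transcripts were not tested. The length of the mRNA itself, which gene models give only roughly, may still account for the steady-state difference, because within the list Spearman's rho between length and difference was 0.52. Loss of Twist1, the biological explanation the design gives, rests on 1 library per group and could not be told from a difference between libraries.

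The second pattern was the turn of macrophage and plasma cell transcripts, lower in the cKO library at steady state and higher after irradiation. A single pool of all other cells carried along in differing amounts was excluded for the steady-state pair, and so as a single cause of both directions. In that pair the neutrophil list lay 2.03 above the macrophage list. After irradiation, where both lists stood high in the cKO library, such a pool was not tested and stays open. A changing amount of macrophage RNA remains possible. The Lineage−Sca1+cKit+CD34−Flk2− gate is meant to remove macrophages and plasma cells alike, but their transcripts were present. Immunoglobulin genes took from 2.71% (irradiated wild type) to 14.7% (steady-state wild type) of reads, and C1qb had 599 FPKM in the steady-state wild-type library. The gate therefore does not count against this explanation. Of 13 list members, 12 were at least 1.5-fold lower at steady state and at least 1.5-fold higher after irradiation. That count restates the pattern, so it lends the explanation no support of its own. Different sets of plasma cells in each library could not be judged. The standard deviation over log2 differences of immunoglobulin V segments was at least 2.53, but antibody repertoires of separate animals may differ whatever the cause. How far they differ within a group was not measured. The macrophage test does not separate RNA carried through the sort from a Twist1-dependent change in these cells.

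The third pattern was the low level of many LT-HSC identity transcripts in both irradiated libraries. Unchanged LT-HSCs diluted with other cells to no less than 5% of the RNA were excluded, since 13 identity transcripts lay below 5% of their steady-state level in both genotypes; stronger dilution stays open. The sex of the animals could not be separated from irradiation, as Ddx3y had at least 10.2 FPKM in the steady-state libraries only. A gate filled with Sca1-negative erythroid progenitors could not be judged and leaves open whether these cells were LT-HSCs. Ly6a kept 16.7% of its level in wild type and 70.7% in cKO, and Kit kept 42.4% and 18.0%. Transcripts did not follow the gate at steady state either, where Cd34 had 18.4 and 29.2 FPKM and Flt3, which encodes Flk2, 6.26 and 9.32 FPKM (wild type first). The Lineage−Sca1+cKit+CD34−Flk2− gate is meant to remove such progenitors, but whether it did is the question left open. Irradiation itself is the biological explanation the design gives, and it remains untested against these.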

How the results depend on the processing

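Tests added only after results were seen are scaling by read totals, centring, removal of markers and immunoglobulin genes, and length matching, the last set before its own result. Over all pairs of a list call and an alternative, the call was kept in 272 of 304 at steady state, 346 of 372 after irradiation, 426 of 440 for irradiation in wild type, 317 of 338 in cKO and 327 of 379 for the difference of differences, with no call turning to the other side. The mean over members kept 6 of 18, 10 of 22, 24 of 26, 17 of 20 and 9 of 24 in the same order. Length matching kept 15 of 18, 22 of 22, 25 of 26, 19 of 20 and 23 of 24. No named gene at least 2-fold apart changed direction, whereas Runx1 after irradiation (−0.10) turned to 0.07 with read totals. Sizes were less stable: over named genes and alternatives, 2995 values moved outside the counting interval of the gene's ratio and 4057 counted as unchanged. Those intervals thus do not cover the choice of scale or pseudocount. Leaving out a doubted library was not possible with 1 library per group, and depth limited scarce genes such as Twist1, whose 2 and 6 reads at steady state left a fold between 0.520 and 29.5. In what follows the cause was not tested, except that raising or lowering the minimum changes the number of genes kept, that leaving out markers or the 50 most abundant genes removes genes, that centring shifts all genes alike, and that rescaling shifts scarce genes less than abundant ones, since 1 is added to each FPKM. For the difference of differences, the mean over members reversed the oxidative phosphorylation list to −0.16 and the immediate early list to −0.0546. The oxidative phosphorylation list at steady state (−0.18) moved to −0.34 without matching and to −0.0735 with the mean; after irradiation (−0.05) it moved to −0.22 without matching, −0.18 with the mean and −0.0711 when matched on all 4 libraries. At steady state, the 46 higher genes became 126 at a minimum of 1 FPKM and with none, 25 at 20 FPKM, 98 without the 50 most abundant genes and 22 without markers and immunoglobulin genes, and the 193 lower genes became 79 in that last setting. After irradiation, the 284 genes higher in cKO became 176 at a pseudocount of 5, 812 at a minimum of 1 and with none, 134 at 20, 614 without the 50 most abundant genes, 470 with read totals, 508 with read totals excluding immunoglobulins, 489 centred and 159 without markers. The 66 lower genes became 102 and 38 at pseudocounts of 0.1 and 5, 125 at a minimum of 1 and with none, 42 at 20, 39 without the 50 most abundant genes, 42 without non-coding symbols, 32 with read totals, 26 excluding immunoglobulins, 30 centred and 39 without markers. For irradiation in wild type, the 1400 higher genes became 2960 with the upper quartile, 750 without the 50 most abundant genes, 922 with read totals and 585 excluding immunoglobulins. The 1401 lower genes became 2424 at a minimum of 1 and with none, 536 at 20, 906 with the upper quartile and 2297 without the 50 most abundant genes. For irradiation in cKO, the 762 higher genes became 1807 at a minimum of 1 and with none, 457 at 20, 1205 with the median of ratios and 2066 with the upper quartile. The 1673 lower genes became 960 at a pseudocount of 5, 2680 at a minimum of 1 and with none, 612 at 20, 861 with the upper quartile and 2625 without the 50 most abundant genes.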

Other observations

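No test in this part was set before its result was seen, and the values are given without explanation. Immunoglobulin transcripts differed in kind as well as amount. Ighm, the IgM constant region, took 5.22% and 3.56% of reads in the wild-type and cKO libraries at steady state and 0.260% and 0.587% after irradiation. Igha, the IgA constant region, took 0.461% and 0.392% at steady state and 0.677% and 2.78% after irradiation. The V segment Igkv14-126 had 320748 and 240836 reads at steady state and 16269 and 28427 after irradiation, and Ighv11-2 had 86680, 83605, 4528 and 8638 in the same order. Igkv12-98 had 28383 reads in the steady-state wild-type library and 405, 0 and 3 in the others, whereas Ighv1-81 was most abundant in the irradiated cKO library (27105 reads, against 4405, 3393 and 6370). Among segments with at least 1000 reads, 6 were at least 2-fold higher and 53 at least 2-fold lower in cKO at steady state (91 segments), and 50 higher and 13 lower after irradiation (82 segments).

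Voltage-gated calcium channel genes had few reads, and 0 of 18 reached 5 FPKM, but 17 of the 18, Cacna1b among them, had a higher FPKM in the irradiated cKO library and 1 a lower. Examples chosen for their large ratios follow: Cacna1a had 89 against 15 reads, Cacnb3 56 against 12, Cacna1f 42 against 10, Cacna1g 17 against 1 and Cacna1i 18 against 0. Others were nearer, with Cacnb1 at 43 against 34 and Cacna2d1 at 10 against 11. In the same libraries, genes seldom transcribed in blood had reads more widely: 112 of 149 vomeronasal receptor genes against 82, and 263 of 354 olfactory receptor genes against 183. At steady state these numbers were 44 and 27 for vomeronasal and 123 and 65 for olfactory receptor genes (cKO and wild type). Of the 18 calcium channel genes, 12 had a higher FPKM in the cKO library at steady state and 6 a lower.

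Kdm5d and Uty, both Y-linked, had 0 reads in the irradiated libraries and lay at least 85.9-fold and 102-fold lower in wild type and at least 83.3-fold and 147-fold lower in cKO at a floor of 3 reads, per library. The Y-linked Eif2s3y had 18.4 and 21.1 FPKM at steady state and 0.0109 and 0.0102 FPKM after irradiation (wild type first). Rpl29 had 18.2 FPKM in the steady-state cKO library against 80.3, 196 and 266 FPKM, and mt-Co1 had 733 FPKM there against 146, 337 and 393 FPKM in the other libraries (steady-state wild type, irradiated wild type, irradiated cKO).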
